A study of Mus musculus with 114 samples.

How the data were processed

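The series holds RNA sequencing libraries from mouse prefrontal cortex, made by the RiboTag method. In this method a haemagglutinin tag on a ribosomal protein is switched on in 1 chosen cell type, and the ribosomes of those cells are pulled down from a tissue lysate with the RNA they carry. Per the labels, the pull-down used an antibody against the tag, cDNA was made with SMART-seq HT, libraries were made with Nextera Flex, and mice were sampled at 6 times of day, given as zeitgeber time (ZT, hours after lights on): ZT2, ZT6, ZT10, ZT14, ZT18 and ZT22. The labels name PV (parvalbumin) and pyramidal cells, and give the sex of each library. The title prefix and the cell type entry name opposite cell types for every library, so libraries are grouped here by the title prefix and called PV-titled and C-titled. The labels do not say whether each library comes from a separate animal. Libraries were treated as separate.

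The values are counts of reads per gene in 1 table deposited by the authors. Per the labels they were made with FastQC and HTSeq against the mouse build GRCm38, and DESeq2 was used for the study's own tests. Versions, the aligner and the annotation are not given in the sources used here. All values were whole numbers, and the table held 13101 gene identifiers, a set already filtered by the authors. Of these, 13051 matched a symbol in the GENCODE vM21 annotation, from which gene positions were taken as well. A count of reads assigned to no gene stood beside them and was used only to describe the libraries. Of 114 libraries in the labels 113 were used. The column left over carried a sex in its name that differs from the title it would fit, and it was left out. Within groups of the same prefix, time and sex no library was a copy of another, and pairs across groups were not compared. The lowest chi-square per gene between 2 libraries of a group was 32.7 in 100 PV-titled pairs and 14.0 in 112 C-titled pairs.

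Library numbers in the titles fall into 2 separate ranges, which were taken as batches. The first range holds 26 PV-titled and 29 C-titled libraries, and the second holds 29 and 29. Each time and sex occurs in both ranges, so the range could be a term of every fit. Replicates are numbered up to 6 within each prefix, time and sex. The numbers follow the order of the titles and so go largely with the range: in C-titled libraries replicates 1 and 2 all lie in the first range, and those from 4 on in the second.

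Tests used R 4.3.3 and edgeR 4.0.16 with TMM scaling, filterByExpr on the groups of prefix, time and sex, and quasi-likelihood F tests. Genes tested numbered 13053 for fits with all libraries, 13047 for PV-titled and 13029 for C-titled libraries. The prefix was tested with time as a factor, sex and range as further terms. On the same fit, glmTreat tested a change of at least 2-fold. Rhythm was tested within each prefix by the cosine and sine of a 24 h period together, with sex and range as further terms. The amplitude is the distance from mean to peak in log2, and the peak is the fitted time of the maximum. Sex was tested on the same fits. Differences in rhythm between prefixes, and between the sexes within a prefix, were tested by the products of prefix or sex with cosine and sine. P values were adjusted by Benjamini and Hochberg over all genes of a test, and 0.05 was the threshold. Overlap of rhythmic genes was tested by a one-sided Fisher exact test. Unless another tool is named, adjusted p values of genes are from edgeR. CPM are the unit of edgeR for counts scaled to the same library total, here after TMM scaling of all libraries together. Shares and counts carry counting error only insofar as reads are separate molecules, which these libraries without molecular identifiers do not show. No interval for counting error is given.

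Gene lists numbered 24: core clock, PV interneuron, GABAergic, pyramidal, other interneuron, astrocyte, oligodendrocyte, microglia, endothelial and mural markers, immediate early genes, heat shock genes, cold-inducible RNA-binding genes, ER (endoplasmic reticulum) chaperones and unfolded protein response, glucocorticoid-responsive genes, glutamate receptors, GABA-A receptors, voltage-gated channels, perineuronal net and matrix genes, sterol synthesis, sex-chromosome genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, cytosolic ribosomal proteins and proteasome subunits. Lists were tested with limma 3.58.1 camera, on the prefix contrast, on the mean of ZT2, ZT6 and ZT10 minus the mean of ZT14, ZT18 and ZT22 within each prefix (day minus night), and on sex within each prefix. The preset correlation of 0.01 was used, and an estimated one as an alternative. Rhythmic genes in a list were also tested for enrichment by a one-sided Fisher exact test against all genes tested. That test treats genes as independent, so its p values are too small where the members of a list vary together. P values were adjusted over the lists of a family. A further set of 11 long noncoding RNAs, taken as nuclear, was compared between the prefixes as a measure of RNA outside ribosomes, and the median log2 difference was taken. Where these RNAs lie in the cell was not measured, and not all of them need be nuclear.

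The grouping, models, tests, lists and thresholds were fixed before the data were examined, and so was the rule for naming genes. That rule takes marker list members, the 10 largest folds each way with at least 10 CPM, all core clock genes, the 10 smallest p and 5 largest amplitudes of each rhythm fit, the 10 smallest p of the rhythm difference and of each sex contrast, the 3 smallest p where no gene passes, and up to 4 members of each list with the smallest p. Some genes that meet the rule are not reported here. Alternatives fixed in advance were DESeq2 size factors, no filter, a filter at a mean of 10 CPM, fits without the range, a replicate block, each range alone, each replicate number left out in turn, DESeq2 1.42.0, limma-trend with a prior count of 1, time as a factor, each sex alone, an unadjusted p under 0.01, and the estimated correlation. The replicate block is a term for the first number in the title, which can differ from the replicate number. Chosen after seeing the data were fits without 8 libraries that stand apart, fits with the first principal component of each prefix as a covariate, and list tests with other scalings. A library was taken to stand apart when its median correlation with the other libraries of its prefix lay over 5 median absolute deviations below the median.

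The fits were tested on simulated data in which 200 genes were changed, 100 at each of 2 sizes. The simulated libraries were drawn independently around the mean level of each gene. They held no range differences, no shared deviations and no libraries that stand apart, so recovery in the real libraries can differ. Of rhythms with an amplitude of 0.5, 85% were called in PV-titled and 93% in C-titled libraries, and with 0.25, 34% and 67%. Of prefix differences of 0.5 in log2, 90% were called. Of rhythm differences between prefixes with an amplitude of 0.5, 74% were called. Of sex differences of 0.5, 80% were called in PV-titled and 89% in C-titled libraries. Each comparison was also repeated on 40 splits of the libraries, the real one among them.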

Results

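RNA bound to tagged ribosomes was sequenced from the prefrontal cortex of female and male mice at 6 times of day, every 4 h from ZT2 to ZT22. The 113 libraries used comprise 55 PV-titled libraries (28 from females, 27 from males) and 58 C-titled libraries (29 from females, 29 from males). Each combination of prefix, time and sex holds 4 or 5 libraries, and each combination of prefix and time 8 to 10. Counts assigned to genes ranged from 19.1 to 39.5 M (megacounts) per PV-titled library (26.7 ± 5.20, mean ± SD, n = 55) and from 24.6 to 44.1 M per C-titled library (34.7 ± 5.02, n = 58). The share of counts that fell on no gene was 61.0% ± 2.78 (SD) in PV-titled and 53.1% ± 1.33 in C-titled libraries. Xist, the RNA that coats the inactive X chromosome, matched the sex label of all 113 libraries.

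In 8 libraries the median correlation with the other libraries of their prefix was far lower than in the rest. They comprise 5 C-titled libraries, all at ZT2 or ZT6 (0.874 to 0.939, against a median of 0.977), and 3 PV-titled libraries at ZT10, ZT14 and ZT22 (0.804 to 0.845, against a median of 0.935). Counts without these 8 libraries, a setting chosen after seeing the data, are given beside several of the results.

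Markers of PV interneurons and of GABAergic neurons were higher in PV-titled libraries, and markers of pyramidal neurons in C-titled libraries. This comparison asks which cell type each title prefix goes with. Pvalb (ENSMUSG00000005716, GRCm38 chromosome 15, 78191114 to 78206400), which encodes parvalbumin, stood at 38.9 ± 18.5 CPM (SD, n = 55) in PV-titled and 1.07 ± 0.918 CPM (n = 58) in C-titled libraries, a 38.2-fold difference (log2 5.26, SE 0.15, adjusted p = 2.07e-54). All 55 PV-titled libraries lay above the C-titled median. Gad1 (ENSMUSG00000070880, chromosome 2, 70553072 to 70602014), which encodes an enzyme of GABA synthesis, was 16.5-fold higher (416 ± 113 against 26.4 ± 14.5 CPM, log2 4.04, SE 0.09, adjusted p = 3e-63, higher in 55 of 55). Slc17a7 (ENSMUSG00000070570, chromosome 7, 45163949 to 45176142), which encodes the vesicular glutamate transporter of cortical pyramidal neurons, was 2.48-fold higher in C-titled libraries (1710.1 ± 555 against 721 ± 288.9 CPM, SE 0.11 in log2, adjusted p = 9.07e-20, 54 of 58 C-titled libraries above the PV-titled median). The marker genes placed PV-titled libraries on the interneuron side and C-titled libraries on the pyramidal side, as the titles do and the cell type entries do not.

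**Figure D1:**
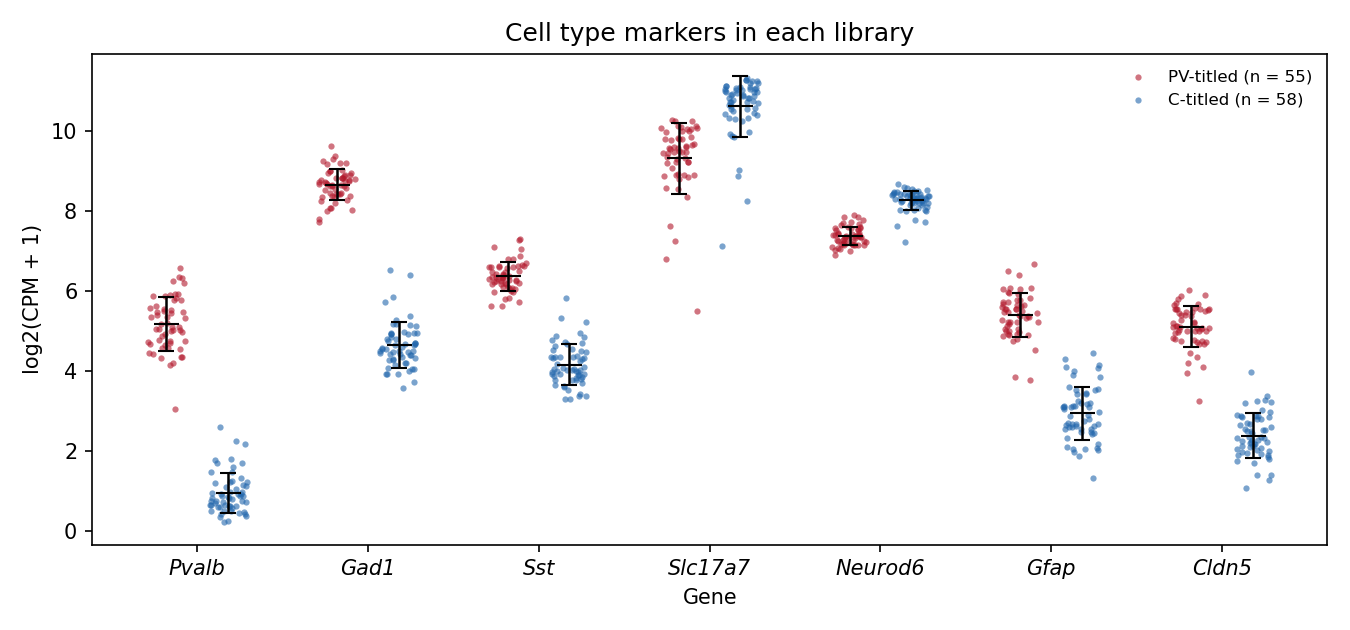
Level of marker genes in each library, as log2 of CPM plus 1, with 1 point per library, and the mean and SD in black. Pvalb had a mean of 38.9 CPM in 55 PV-titled and 1.07 CPM in 58 C-titled libraries, and Slc17a7 means of 721 and 1710.1 CPM.

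Among PV interneuron markers 11 of 12 were higher in PV-titled libraries (11 with p adjusted over the list alone), with a median log2 difference of 3.53. Cox6a2, a muscle-type subunit of cytochrome oxidase, was 52.7-fold higher, Tac1, the precursor of substance P, 42.7-fold, and Syt2, a synaptotagmin, 38.2-fold. All 8 GABAergic markers were higher (8 adjusted over the list alone, median log2 3.62). They included Slc32a1, the vesicular GABA transporter (log2 4.65, SE 0.17), and Gad2 (log2 3.30). By camera with the preset correlation the adjusted p was 1.3e-06 for PV interneuron and 4.02e-06 for GABAergic markers, and for both adjusted p = 0.0578 with an estimated correlation. Of 12 pyramidal markers 11 were lower in PV-titled libraries (11 adjusted over the list alone, median log2 -1.02), among them Sv2b, a synaptic vesicle protein (log2 -1.63), and Nrgn, neurogranin (log2 -1.48). Cux2, of upper cortical layers, did not pass (log2 -0.07, adjusted p = 0.39). The camera adjusted p was 0.000631, and adjusted p = 0.0514 with an estimated correlation.

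Markers of other cell types were also higher in PV-titled libraries. All 10 astrocyte, 8 oligodendrocyte, 10 microglia and 9 endothelial and mural markers that were tested passed, and the same numbers passed when adjusted over the list alone. Their median log2 differences were 2.04, 2.34, 2.33 and 2.67. Slc1a3, an astrocyte glutamate transporter, stood at 229 ± 41.0 against 51.6 ± 21.3 CPM, and Cldn5, an endothelial tight junction protein, at 35.5 ± 11.6 against 4.62 ± 2.36 CPM. Of other interneuron markers 9 of 10 were higher (10 differed when adjusted over the list alone, median log2 2.39), with Sst, somatostatin, at 83.9 ± 23.1 against 18.05 ± 8.13 CPM. Lamp5 was the member lower in PV-titled libraries (log2 -1.61). Camera gave adjusted p values of 0.000137 for astrocyte, 0.00161 for oligodendrocyte, 1.43e-05 for microglia, 8.91e-05 for endothelial and mural and 0.00039 for other interneuron markers. In the same order the lists had adjusted p = 0.0608, 0.114, 0.0514, 0.0668 and 0.0578 with an estimated correlation. All 11 mitochondrially encoded genes were higher (11 adjusted over the list alone, median log2 2.43, camera adjusted p = 2.69e-05, adjusted p = 0.148 with an estimated correlation), as were all 11 long noncoding RNAs taken as nuclear, with Malat1 at 6748 ± 4398 against 1263 ± 2502 CPM.

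Heat shock, ER chaperone and nuclear oxidative phosphorylation genes were mostly lower in PV-titled than in C-titled libraries. All 14 heat shock genes were lower (14 adjusted over the list alone, median log2 -1.02, camera adjusted p = 1.62e-06, adjusted p = 0.0514 with an estimated correlation), with Hsp90ab1, a cytosolic chaperone, at log2 -1.47. Of 15 ER chaperones 14 were lower and 1 higher (15 adjusted over the list alone, median log2 -1.14, camera adjusted p = 1.81e-05, adjusted p = 0.0578 with an estimated correlation), with Hspa5, the main ER chaperone, at log2 -1.60. Nuclear oxidative phosphorylation genes were lower in 75 of 78 and higher in 2 (77 adjusted over the list alone, median log2 -0.70, camera adjusted p = 5.69e-11, adjusted p = 0.261 with an estimated correlation). Proteasome subunits were lower in 34 of 35 and higher in 1 (35 adjusted over the list alone, median log2 -0.87, camera adjusted p = 5.69e-11, adjusted p = 0.0578 with an estimated correlation). Cytosolic ribosomal proteins were lower in 70 of 78 and higher in 4 (74 adjusted over the list alone, median log2 -0.55, camera adjusted p = 1.07e-06, adjusted p = 0.435 with an estimated correlation). Sterol synthesis genes were lower in 15 of 20 and higher in 2 (17 adjusted over the list alone, median log2 -0.61, camera adjusted p = 0.00442, adjusted p = 0.0578 with an estimated correlation). GABA-A receptor genes were lower in 9 of 12 and higher in 2 (11 adjusted over the list alone, median log2 -0.71, camera adjusted p = 0.00779, adjusted p = 0.148 with an estimated correlation).

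Members of the remaining lists went both ways. Core clock genes were higher in PV-titled libraries in 6 and lower in 10 of 19 (16 adjusted over the list alone, camera adjusted p = 0.227). Immediate early genes were higher in 3 and lower in 12 of 20 (15 adjusted over the list alone, camera adjusted p = 0.162), with Bdnf, a neurotrophin, at log2 -1.53. Glutamate receptors were higher in 7 and lower in 11 of 22 (18 adjusted over the list alone, camera adjusted p = 0.704). Voltage-gated channels were higher in 12 and lower in 13 of 32 (25 adjusted over the list alone, median log2 -0.01, camera adjusted p = 0.901 with an upward direction). Glucocorticoid-responsive genes were higher in 6 and lower in 4 of 13 (10 adjusted over the list alone, camera adjusted p = 0.815). Perineuronal net and matrix genes were higher in 4 and lower in 2 of 7 (6 adjusted over the list alone, camera adjusted p = 0.135), with Bcan, brevican, at log2 2.53. Of the cold-inducible genes Cirbp was lower (log2 -0.52) and Rbm3 higher (log2 0.88), so 2 differed when adjusted over the list alone (camera adjusted p = 0.961). Sex-chromosome genes were higher in 3 and lower in 2 of 6 (5 adjusted over the list alone, camera adjusted p = 0.519). Outside the lists, the genes with the largest folds toward C-titled libraries included Cck, cholecystokinin (201.3 ± 47.9 against 1002 ± 349 CPM), Ccn3 (log2 -2.34) and Wfs1, an ER membrane protein (log2 -2.15). Those toward PV-titled libraries included Rerg, a Ras-like GTPase (27.5-fold), and Tmem132c (22.1-fold).

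In all, 11419 of 13053 genes differed between the prefixes, 5785 higher in PV-titled and 5634 higher in C-titled libraries. At least 2-fold differences passed for 2936 genes, 2344 of them higher in PV-titled libraries. By library-number range, the first and second alone gave 10398 and 11109 genes, and Pvalb differed by log2 4.87 and 5.63. Counts left without TMM scaling moved the median of all genes from -0.02 to 0.18 in log2.

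Rhythmic genes in PV-titled libraries were enriched for core clock, immediate early and ER chaperone genes, and the called members of these lists peaked in the night. The question here is which genes follow the time of day in the libraries of each prefix. PV-titled libraries also held markers of other cell types, so their rhythms cannot be assigned to PV cells alone. Ciart (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251), a repressor in the clock, had an amplitude of 0.93 in log2 (SE 0.07, n = 55), 3.61-fold from trough to peak, with a peak at ZT12.4 (adjusted p = 1.97e-13). Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a clock output transcription factor, had an amplitude of 0.64 (SE 0.05) and a peak at ZT13.5 (adjusted p = 2.31e-12). Per2, of the negative limb, peaked at ZT17.9 (amplitude 0.65, SE 0.08, adjusted p = 9.94e-07), and Arntl, of the positive limb, at ZT23.5 (amplitude 0.30, SE 0.05, adjusted p = 9.59e-05). Of 19 core clock genes 12 were called, all with a peak from ZT12 to ZT24 (15 adjusted over the list alone, Fisher adjusted p = 6.58e-13). Per3 (adjusted p = 0.0778), Nfil3 (0.073) and Cry2 (0.216) were among those that did not pass.

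**Figure D2:**
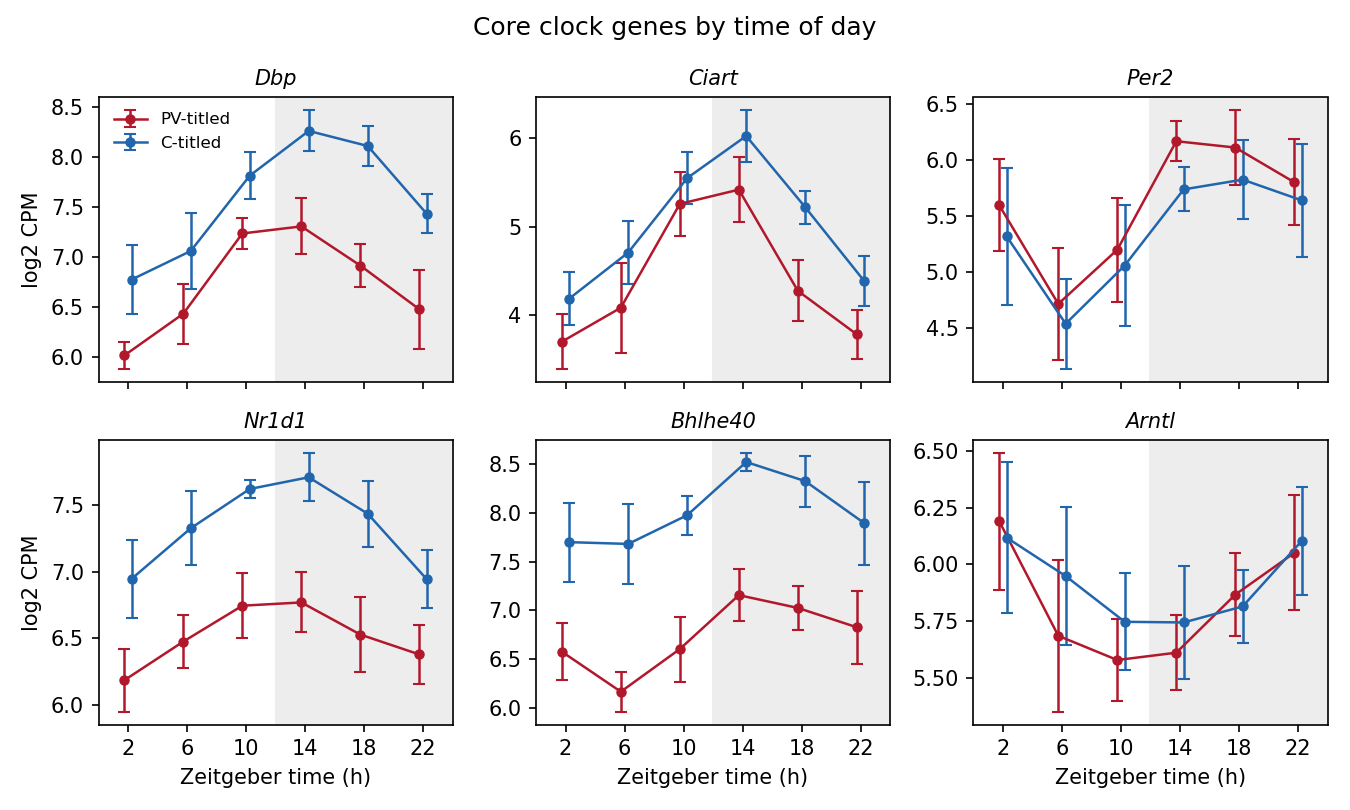
Core clock genes by zeitgeber time, as the mean and SD of log2 CPM in PV-titled and C-titled libraries, with 8 to 10 libraries per point and the dark hours shaded. Dbp had its fitted peak at ZT13.5 in PV-titled and at ZT15.0 in C-titled libraries, and Arntl at ZT23.5 and ZT0.731.

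Immediate early genes, which are induced by neuronal activity, were called in 7 of 20 in PV-titled libraries, all with night peaks (15 adjusted over the list alone, Fisher adjusted p = 1.13e-05, 10 called without the libraries that stand apart). Arc, a regulator of synaptic strength, had an amplitude of 0.99 (SE 0.16), 3.95-fold from trough to peak, at ZT18.3 (adjusted p = 0.000396). Nr4a1 (amplitude 0.52, ZT19.5), Egr1 (0.56, ZT19.8) and Homer1 (0.36, ZT21.7) followed. ER chaperones were called in 7 of 15, all with night peaks (10 adjusted over the list alone, Fisher adjusted p = 1.61e-06), with Hspa5 at an amplitude of 0.40 (SE 0.06, ZT19.8, adjusted p = 1.5e-05) and Sdf2l1 at 0.48 (ZT18.3). Other lists had few called members and no enrichment: heat shock genes 2 of 14 (6 adjusted over the list alone, Fisher adjusted p = 0.272), glucocorticoid-responsive genes 2 of 13 (6 adjusted over the list alone, 0.272), cold-inducible genes 1 of 2 (2 adjusted over the list alone, 0.272), and 1 each of pyramidal markers, other interneuron markers and voltage-gated channels. The remaining 15 lists had 0 called by edgeR. Pvalb itself was not called (amplitude 0.26, adjusted p = 0.413).

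Outside the clock list the smallest p values belonged to Cirbp, a cold-inducible RNA-binding protein (amplitude 0.46, SE 0.05, ZT8.61, adjusted p = 4.87e-09), Nptx1, a neuronal pentraxin (0.63, ZT20.0, adjusted p = 1.11e-07), and Ccnd2, a D-type cyclin (0.40, ZT16.0, adjusted p = 3.49e-07). Hrh3, a histamine receptor, peaked at ZT16.0 (amplitude 0.44). Among the largest amplitudes, Abhd2 had 0.90 (adjusted p = 0.0443) but 0.52 without the libraries that stand apart (adjusted p = 0.28).

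By day minus night means with camera in PV-titled libraries, core clock genes (median log2 -0.24, adjusted p = 2.39e-12, and adjusted p = 2.06e-06 with an estimated correlation), immediate early genes (-0.41, 9.51e-12, and adjusted p = 0.0184 with an estimated correlation) and ER chaperones (-0.24, 2.39e-12, and adjusted p = 0.00301 with an estimated correlation) were lower by day. Cold-inducible genes were higher by day (0.36, 4.85e-05, and adjusted p = 0.00301 with an estimated correlation). Nuclear oxidative phosphorylation genes (0.08, 1.35e-05) and PV interneuron markers (0.16, 0.0461) passed with the preset value, and both had adjusted p = 0.715 with an estimated correlation.

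In all, 404 of 13047 genes (3.10%) were rhythmic in PV-titled libraries, with a median amplitude of 0.29, and 41.6% of them peaked from ZT0 to ZT12. The peaks were most frequent from ZT16 to ZT20 (136 genes) and from ZT4 to ZT8 (108 genes). Within the first and second range alone 20 and 40 genes were called, and leaving out replicate 1, 2, 3, 4 or, in the groups that have it, 5 gave 1.95%, 1.41%, 1.249%, 1.19% and 2.01% of genes. Without the libraries that stand apart the count was 530, of which 373 were among the 404. With time as a factor, and in each sex alone, fewer genes were called, as given in percent below.

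In C-titled libraries many more genes were called, core clock genes among them. Dbp had an amplitude of 0.76 (SE 0.04, n = 58), 2.86-fold from trough to peak, with a peak at ZT15.0 (adjusted p = 2.27e-20), and Ciart 0.91 (SE 0.05) at ZT13.2 (adjusted p = 2.74e-19). Nr1d1, a repressor that binds the Arntl gene, peaked at ZT12.4 (amplitude 0.42, SE 0.04, adjusted p = 7.49e-11), Per2 at ZT18.6 (0.59, SE 0.08), Cry1 at ZT19.0 (0.35, SE 0.05) and Arntl at ZT0.731 (0.22, SE 0.04). Of 19 core clock genes 17 were called, 13 with a peak from ZT12 to ZT24 and 4 from ZT0 to ZT12 (17 adjusted over the list alone, Fisher adjusted p = 4.79e-07, 15 without the libraries that stand apart). Per3 (adjusted p = 0.146) and Rora (0.911) were not. Immediate early genes were called in 15 of 20 (16 adjusted over the list alone, Fisher adjusted p = 0.000126), 13 with night peaks. Arc had an amplitude of 1.02 (SE 0.19) at ZT16.2 and Jun 0.59 (SE 0.09) at ZT19.1. ER chaperones were called in 11 of 15, all with night peaks (12 adjusted over the list alone, Fisher adjusted p = 0.00194), among them Pdia4 (0.40, ZT19.4) and Hspa5 (0.37, ZT19.8). Heat shock genes were called in 9 of 14 (11 adjusted over the list alone, Fisher adjusted p = 0.0183), with Hspa1b at 0.59 (ZT21.1) and Chordc1 at 0.37 (ZT21.7). Without the libraries that stand apart these 3 lists had 15, 12 and 9 called. Their members vary together, with estimated correlations of 0.34, 0.22 and 0.13 in the day minus night fit, which the Fisher test leaves out.

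Glucocorticoid-responsive genes were called in 8 of 13 (8 adjusted over the list alone, Fisher adjusted p = 0.0372, 8 without the libraries that stand apart). Fkbp5, a chaperone of the glucocorticoid receptor, peaked at ZT15.0 (amplitude 0.42, SE 0.05, adjusted p = 4.1e-07). Both cold-inducible genes were called, Cirbp with a peak at ZT9.58 (0.49, SE 0.05) and Rbm3 at ZT11.5 (0.54, SE 0.06), with 2 adjusted over the list alone and Fisher adjusted p = 0.194. Nuclear oxidative phosphorylation genes were called in 34 of 78, all with peaks from ZT0 to ZT12 (52 adjusted over the list alone, Fisher adjusted p = 0.00682), but in 1 of 78 without the libraries that stand apart. Uqcrfs1, of complex III, went from an amplitude of 0.17 to 0.09. Sterol synthesis genes were called in 9 of 20 (11 adjusted over the list alone, Fisher adjusted p = 0.192), and in 10 without those libraries (adjusted p = 0.0213). Hmgcs1, an early enzyme of the pathway, peaked at ZT5.13 (amplitude 0.15, SE 0.03), while Insig1, a sterol sensor, went from 0.96 to 0.22 (adjusted p = 0.241) without those libraries. No other list was enriched. Among them 5 of 12 pyramidal markers were called (Emx1, 0.31 at ZT8.99), 8 of 22 glutamate receptors, 8 of 32 voltage-gated channels, 8 of 35 proteasome subunits (2 without those libraries), 9 of 78 cytosolic ribosomal proteins (1 without them), 4 of 10 astrocyte markers (0 without them) and 4 of 6 sex-chromosome genes (2 without them).

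The smallest p values outside the clock list in C-titled libraries belonged to Sphk2, a sphingosine kinase (amplitude 0.45, SE 0.04, ZT15.0, adjusted p = 2.78e-13), Klhl40 (0.62, ZT10.9, adjusted p = 4.2e-11), Pcsk4, a proprotein convertase (0.67, ZT15.2, adjusted p = 5.19e-11), and Cplx3, a complexin of the synaptic vesicle machinery (0.74, ZT15.2, adjusted p = 2.36e-09). Several of the largest amplitudes were smaller without the libraries that stand apart. Egfl8 went from 1.68 to 0.31 (adjusted p = 0.195), Cdkn1b, a cyclin-dependent kinase inhibitor, from 1.503 to 0.28 (0.512), Rpgrip1 from 1.48 to 0.49 (0.257), and Abhd2 from 1.45 to 0.61 (0.0186).

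By day minus night means in C-titled libraries, core clock genes were lower by day (median log2 -0.28, camera adjusted p = 2.27e-07, and with an estimated correlation adjusted p = 0.00513, or 0.0512 without scaling). Immediate early genes (-0.57, 2.54e-08, and adjusted p = 0.129 with an estimated correlation) and ER chaperones (-0.23, 4.77e-06, and adjusted p = 0.104 with an estimated correlation) went the same way with the preset value. Passing upward with the preset value were nuclear oxidative phosphorylation genes (0.19, 1.27e-13, and adjusted p = 0.431 with an estimated correlation), ribosomal proteins (0.15, 2.54e-08, and adjusted p = 0.921 with an estimated correlation), proteasome subunits (0.06, 0.0333, and adjusted p = 0.952 with an estimated correlation) and sex-chromosome genes (0.24, 0.00269, and adjusted p = 0.104 with an estimated correlation). Without the 5 C-titled libraries that stand apart, all on the day side of this contrast, the medians of these 4 lists were 0.08, 0.06, 0.02 and 0.18, and proteasome subunits did not pass (adjusted p = 0.621).

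In all, 3518 of 13029 genes (27.0%) were rhythmic in C-titled libraries, with a median amplitude of 0.19. Of these, 1195 (34.0%) peaked from ZT4 to ZT8. Without the libraries that stand apart 2864 genes were called, 2233 of them among the 3518, and 15.2% of the 2864 peaked from ZT4 to ZT8. By range, 378 genes were called in the first alone and 1334 in the second, and without replicate 3 of every group 1801. With time as a factor 1307 genes were called, and fewer still in each sex alone.

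**Figure D3:**
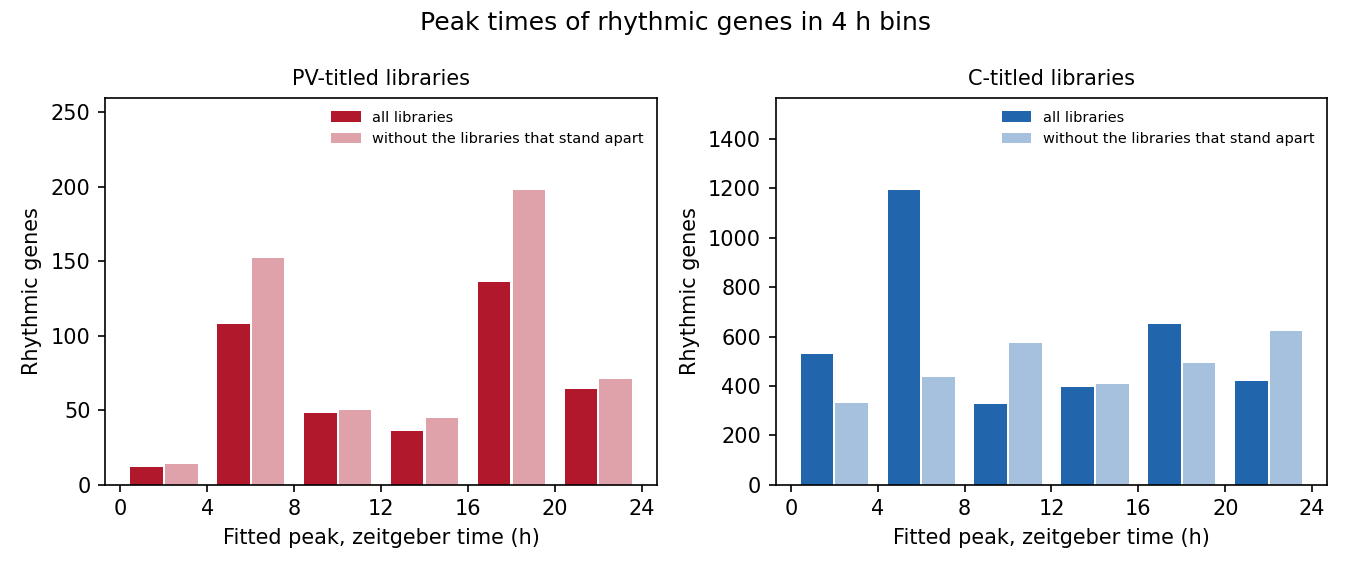
Number of rhythmic genes by fitted peak in 4 h bins, for PV-titled and C-titled libraries, with all libraries and without those that stand apart. In C-titled libraries the bin from ZT4 to ZT8 held 1195 genes with all libraries and 435 without the 5 that stand apart.

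Of genes tested in both prefixes 280 were rhythmic in both (361 without the libraries that stand apart), against 109 expected for independent lists (odds ratio 6.54, one-sided Fisher exact p = 1.57e-72 across genes, which are not independent replicates). The peaks lay within 2 h of each other for 73.2% and within 4 h for 95% of these genes, and 4 genes were over 6 h apart. Ciart, Dbp, Per2, Bhlhe40, Arntl, Cirbp, Arc and Hspa5 were among the shared genes. Whether the shared rhythms come from the named cell types or from RNA of other cells in the libraries was not tested. Within the first and second range alone 8 and 21 genes were shared, and leaving out replicate 1, 2, 3, 4 or 5 gave 1.22%, 0.883%, 0.875%, 0.821% and 1.26% of genes, against 2.15% with all.

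The rhythm itself differed between the prefixes for 73 of 13053 genes, by the test of the difference. Rnpep (ENSMUSG00000041926, chromosome 1, 135262712 to 135284084), an aminopeptidase, had the smallest p (difference vector 0.32 in log2, SE 0.05, adjusted p = 1.53e-05). It peaked at ZT4.57 in PV-titled (amplitude 0.19) and ZT20.7 in C-titled libraries (amplitude 0.19). Ctps2, an enzyme of cytidine nucleotide synthesis, peaked at ZT11.8 and ZT20.0 (adjusted p = 0.000216), and Klhl7 at ZT6.62 and ZT19.0 (adjusted p = 0.00156). Rbm3 had an amplitude of 0.54 in C-titled and 0.16 in PV-titled libraries, where it was not called (adjusted p of the difference 0.0019). Zfp46 had the larger amplitude in PV-titled libraries, 0.51 against 0.19 (adjusted p = 0.000184). Of the 73 genes 57 were called rhythmic in C-titled libraries only, and the fitted amplitude was larger there for 59 and in PV-titled libraries for 14. Of the 280 genes rhythmic in both it was larger in PV-titled libraries for 75.4%. Both tallies depend on how the genes were selected. Colgalt1 (0.37, adjusted p = 0.00206), Sars, a seryl-tRNA synthetase (0.21, adjusted p = 0.00206), and Ubash3b (0.69, adjusted p = 0.00259) also passed.

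The largest of the named differences, Egfl8 (2.31), had adjusted p = 0.889 without the libraries that stand apart, while the other genes named here for their rhythm difference, apart from Dbp, passed. No list was enriched, and 1 member each passed of cold-inducible (Fisher adjusted p = 0.268), core clock, heat shock and sterol synthesis genes (0.637 each). The core clock member was Dbp (adjusted p = 0.0352, and 0.0997 without the libraries that stand apart). The count was 18 without those libraries, 15 of them among the 73. Within the first and second range alone it was 0 and 2 by edgeR, against 1759 genes at an unadjusted p under 0.05 with all libraries, and DESeq2 and limma called 1.203% and 0.146% of genes, against 0.559% by edgeR. Leaving out replicate 1, 2, 3, 4 or 5 gave 15, 21, 3, 30 and 103.

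X-linked genes known to escape inactivation were higher in females. All 6 sex-chromosome genes tested are X-linked. No Y-linked member of the list was tested, so a higher level in males could not be seen for such genes. In PV-titled libraries 4 genes passed, all higher in females. Xist (ENSMUSG00000086503, X chromosome, 103460366 to 103483254) was at 422 ± 242.1 CPM in 28 female and 1.61 ± 2.34 CPM in 27 male libraries (log2 7.88, SE 0.36, adjusted p = 5.82e-20, higher in 28 of 28). Tsix, its antisense transcript, had a log2 difference of 7.69. The strand of the reads is not given in the sources used here, so these overlapping genes cannot be separated. Eif2s3x, a translation initiation factor, was 1.67-fold higher (adjusted p = 1.34e-05, 27 of 28 above the male median) and Ddx3x, an RNA helicase, 1.31-fold (adjusted p = 0.0216, 26 of 28). Adjusted over the list alone, all 6 sex-chromosome genes passed. Within the first and second range alone 2 and 4 genes were called.

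In C-titled libraries 24 genes passed, 18 higher in females. Xist (log2 9.37, SE 0.29, adjusted p = 3.66e-40), Tsix (8.95), Eif2s3x (1.60-fold, adjusted p = 4.04e-15), Ddx3x (1.22-fold, adjusted p = 0.00116) and Kdm6a, a histone demethylase (1.30-fold, adjusted p = 0.00519), were higher in females, so 5 of 6 sex-chromosome genes passed (6 adjusted over the list alone). Rbm3 (ENSMUSG00000031167, X chromosome, 8138975 to 8145880) was 1.45-fold higher in males (52.7 ± 16.2 against 35.4 ± 12.8 CPM, n = 29 each, log2 -0.54, SE 0.09, adjusted p = 0.000128, 23 of 29 males above the female median). Cited4, a transcriptional coactivator, was also higher in males (log2 -0.37, adjusted p = 0.0018). Abi3bp (0.44, adjusted p = 0.00219) and Pdyn, prodynorphin (0.28, adjusted p = 0.0125, 26 of 29 females above the male median), were higher in females. The other lists had 0 to 2 members that passed adjusted over the list alone.

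The count was 91 without the libraries that stand apart, which held all 24. Within the first and second range alone it was 7 and 4, and without replicate 1, 2 or 4 of every group 11, 8 and 13. Kdm5c had log2 0.66 (adjusted p = 0.0852) with all libraries and 0.42 (adjusted p = 8.5e-06) without those that stand apart.

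By camera for female minus male, sex-chromosome genes passed in PV-titled (median log2 0.68, adjusted p = 3.97e-61, and adjusted p = 6.09e-20 with an estimated correlation) and C-titled libraries (0.60, 1.27e-68, and adjusted p = 1e-17 with an estimated correlation). Core clock genes passed upward in PV-titled libraries (0.08, 0.00131, and adjusted p = 0.0396 with an estimated correlation), where 0 of 19 members passed singly by edgeR. With an estimated correlation the list had adjusted p = 0.0506 without the libraries that stand apart and 0.247 without scaling. Cold-inducible genes passed downward in C-titled libraries (-0.42, 8.38e-08, and adjusted p = 0.000302 with an estimated correlation). In PV-titled libraries PV interneuron markers (-0.09, 0.0243), immediate early genes (0.09, 0.0243), ER chaperones (0.08, 0.0108), oxidative phosphorylation genes (-0.05, 0.000284) and ribosomal proteins (-0.07, 1.45e-07) passed with the preset value, with adjusted p = 0.836, 0.834, 0.647, 0.91 and 0.834 with an estimated correlation. In C-titled libraries glutamate receptors (0.08, 0.00578), oxidative phosphorylation genes (-0.06, 6.71e-07) and proteasome subunits (-0.06, 4.6e-07) did so, with adjusted p = 0.29, 0.993 and 0.478 with an estimated correlation.

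No gene passed the edgeR test for a rhythm that differs between females and males, in PV-titled libraries (0 genes, 707, or 5.42%, at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma) or in C-titled libraries (0 genes, 1.34% at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma). In PV-titled libraries the smallest p belonged to Ehmt1, a histone methyltransferase (adjusted p = 0.147), with fitted peaks at ZT18.6 in males and ZT10.5 in females. In C-titled libraries Trim30a, Sept4 and Pwwp2b had the smallest p (adjusted p = 0.9997 for each). The 1.34% in C-titled libraries lies under the share of 0.05 that a test gives where no rhythm differs. In simulated data, differences in rhythm with an amplitude of 0.5 were recovered in 22% of cases in PV-titled and 59% in C-titled libraries. With an amplitude of 0.25 the shares were 0% and 15%. The simulated libraries were independent and held none that stand apart, so recovery in the real libraries can differ.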

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

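The test that leaves out the libraries that stand apart was chosen only after the result was seen, as were the other splits of the rhythm difference.

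Within groups of 4 or 5 libraries, 19 of 120 group tests over 5 measures held a library far from the others. For normally distributed values chance puts about 1 in 20 groups there, and so about 6. The flagged libraries all lay high for Pvalb and all low for the correlation, and the 5 measures share libraries. The excess over 6 is therefore no test of more outlying libraries than by chance. The total of gene counts was 34.5 M (megacounts) in PV ZT10 F replicate 2, against 24.8 M in the next library. The share of counts on no gene was 54.9% in C ZT18 F replicate 1, 59.4% in C ZT2 M replicate 4 and 58.8% in C ZT6 F replicate 5. The median correlation with the other libraries of the prefix was 0.874 in C ZT2 F replicate 3, 0.909 in C ZT2 M replicate 4, 0.958 in C ZT22 M replicate 1 and 0.935 in C ZT6 M replicate 3. In PV-titled libraries it was 0.922 in ZT10 M replicate 2, 0.845 in ZT22 M replicate 2 and 0.895 in ZT6 F replicate 1. Pvalb was at 1.78 CPM in C ZT10 M replicate 1, 5.05 CPM in C ZT18 F replicate 1, 3.48 CPM in C ZT22 M replicate 1 and 2.41 CPM in C ZT6 F replicate 4. In PV-titled libraries Pvalb was at 59.3 CPM in ZT10 F replicate 3, 79.1 CPM in ZT18 M replicate 3 and 57.6 CPM in ZT22 F replicate 2. Slc17a7 was at 520.5 CPM in C ZT22 M replicate 1, against 1927 CPM in the next library.

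In C-titled libraries 34.0% of rhythmic genes peaked from ZT4 to ZT8. The 5 libraries at ZT2 and ZT6 that stand apart are a candidate explanation, since without them the share was 15.2%. The genes with these peaks differed from the other called genes by -2.45 points in median GC content (95% bootstrap interval over genes -3.14 to -1.80) and by -0.44 in log2 transcript length (-0.54 to -0.34). Both differences lay between the bounds set for and against these properties, so GC content and gene length cannot be told apart from the other explanations for these genes. A true daytime peak of the genes concerned, which the design's sampling times name, stays open as untested.

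The rhythm of 73 genes differed between PV-titled and C-titled libraries by the test of the difference. The difference vectors of the 9 genes with the smallest p were 0.32 for Rnpep, 0.50 for Zfp46, 0.36 for Ctps2, 0.31 for Klhl7, 2.31 for Egfl8, 0.50 for Rbm3, 0.37 for Colgalt1, 0.21 for Sars and 0.69 for Ubash3b in log2. Of 40 splits of the libraries, the real one included, 3 gave as many genes, with the highest other at 1.33% of the genes tested against the real 0.559%, so chance could not be excluded for the count. Another split gave 160 genes. Counts of this size in splits that ignore the prefix point to some structure of the samples, whose source was not tested.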

How the results depend on the processing

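The fits without the libraries that stand apart and with the first principal component as a covariate, and the list tests with other scalings, were chosen only after the results were seen. In the alternatives fixed in advance the count of genes that differ between the prefixes stayed from 9036 to 11455, against 11419, and PV-titled libraries held 48.8% to 51.6% of the higher calls in every fit run. All these fits used TMM or DESeq2 scaling, which centres the genes, so this balance follows in part from the scaling. At least 2-fold, 2344 of 2936 genes were higher in PV-titled libraries. Of the named genes that passed, all but 1 in the prefix contrast kept their direction and call in every fit run, against 5 of 38 rhythms in PV-titled and 22 of 94 in C-titled libraries, 0 of 13 rhythm differences, and 2 of 4 and 4 of 15 sex differences. Smaller sets of libraries test with less power by construction; for the other changes the cause was not tested.

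With a mean of at least 10 CPM, which tests fewer genes, 1731 genes differed at least 2-fold. Rhythms are given here as percent of the genes tested, against 3.10% in PV-titled, 27.0% in C-titled, 2.15% in both, and 0.559% for the rhythm difference. In the first range alone the rhythmic genes were 0.153% in PV-titled, 2.90% in C-titled and 0.0614% in both, the rhythm differences 0 by edgeR, and the sex differences 2 and 7 genes. In the second range alone the rhythmic genes were 0.307%, 10.2% and 0.161%, the rhythm differences 0.0153%, and the sex differences in C-titled libraries 4 genes. With time as a factor 1.196% of genes passed in PV-titled and 10.03% in C-titled libraries, in females alone 0.997% and 2.07%, and in males alone 0.0613% and 3.63%. At an unadjusted p under 0.01 7.28% were rhythmic in PV-titled libraries, 3.87% in both, and 4.82% differed in rhythm. Rhythm differences came to 1.71% without the range as a term, 0.153% with the replicate block, 0.146% by limma, 1.203% by DESeq2, 0.138% without the libraries that stand apart and 0.115% with the first principal component. Sex differences in C-titled libraries numbered 39 by DESeq2, 91 without the libraries that stand apart and 57 with the first principal component. DESeq2 called 1 rhythm difference between the sexes in PV-titled libraries. List tests passed 41 times with the preset and 9 times with an estimated correlation.

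Leaving out each replicate number in turn, in the groups that have it, gave 1.19% to 2.01% of genes as rhythmic in PV-titled libraries, 13.8% to 23.9% in C-titled libraries and 0.821% to 1.26% in both. It gave 0.0230% to 0.789% rhythm differences, and 3 to 5 and 8 to 18 genes with sex differences in PV-titled and C-titled libraries. Rhythms in C-titled libraries whose fitted peak moved by more than 6 h were Cdkn1b (amplitude 0.0423), Insig1 (0.0457) and Scn2b (0.0664) with the first principal component, and Insig1 and Scn2b without replicate 3, where leaving out replicates gave amplitudes of 0.0694 to 1.09 and 0.0539 to 0.822. Libraries of the same first title number were treated as separate in the main fits, although 47.4% of such PV-titled and 68.8% of such C-titled pairs had correlated deviations over 0.1. They resembled each other in part, as a hint from the data. When correlations with other groups were averaged by title number, the own number had the highest mean for 30 of 55 and 36 of 58 libraries. The mean correlation of same-number pairs was 0.0892 and 0.211, against 0.0779 and 0.0885 for other numbers of the same range. The main fits may thus treat dependent libraries as independent. With the title number as a term, the replicate block, 20 genes differed in rhythm between the prefixes against 73, with 19 in common. Rhythmic genes then numbered 434 against 404 in PV-titled and 3311 against 3518 in C-titled libraries. Depth was not the limit of the rhythm counts in C-titled libraries, where 3454 genes passed after counts were thinned to the PV-titled median.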

Other observations

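The test of the spread between libraries, the unscaled marker lists, and the splits of the prefix contrast and of the rhythm difference were chosen only after the results were seen.

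Among receptor and channel genes in the prefix contrast, Grik1, a kainate receptor subunit, was 8.86-fold higher in PV-titled libraries (14.3 ± 4.04 against 1.64 ± 0.698 CPM, higher in 55 of 55), and Grin2c, an NMDA receptor subunit, 5.64-fold. Scn1a, a sodium channel of fast-spiking interneurons, stood at 135 ± 35.8 against 45.3 ± 9.58 CPM (log2 1.55, SE 0.05), and Kcnc2, a fast potassium channel, at log2 1.90. Grm2, a metabotropic glutamate receptor, was 2.63-fold higher in C-titled libraries (log2 -1.39, SE 0.07), and the GABA-A receptor gene Gabra5 had a log2 difference of -0.96. Of matrix genes Hapln1 had 2.99 and Vcan 2.53 in log2.

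More genes were rhythmic in C-titled (3518) than in PV-titled libraries (404). Lower depth of PV-titled libraries is argued against, since 3454 genes passed in C-titled libraries thinned to the same median depth. A larger spread between PV-titled libraries is a candidate explanation: the residual SD was larger by a median ratio of 1.34 (95% bootstrap interval over genes 1.33 to 1.35), and larger for 79.2% of genes. All intervals in this paragraph resample genes, not libraries, so they leave out the variation between libraries. Without the libraries that stand apart, 593 genes called in C-titled libraries of the first range could be measured in the second. There, the rhythms of both prefixes were projected onto the peak time found in the selecting libraries, so a shifted peak also lowers the value. The median projected amplitude in PV-titled libraries was 0.661 of that in C-titled ones (0.565 to 0.732). For 1495 genes called in C-titled libraries of the second range and measured in the first, the ratio was 1.36 (1.27 to 1.45). For genes called in PV-titled libraries the ratios were 0.804 (0.700 to 1.07) and 1.29 (0.959 to 1.77). The bound set in advance named only genes called in C-titled libraries of the first range, and 0.661 met it. Neither the reverse direction nor the omission of libraries was part of that bound. The 2 directions disagree, so smaller amplitudes cannot be told apart from a difference between the ranges. A difference between the cell types themselves, which the design names, stays open as untested.

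Markers of glia, vessels and other interneurons were higher in PV-titled libraries. The TMM factors do not account for this, since without them the lowest median of the 5 lists was 2.26 in log2. Leaving them out moved the median of all genes only from -0.02 to 0.18, too little to change the lists much. Other effects of scaling to library totals were therefore not tested. A larger share of RNA not held by tagged ribosomes is a candidate explanation. Long noncoding RNAs taken as nuclear had a median log2 difference of 2.69, with 11 of 11 higher. This is close to the 2.06 to 2.62 of the marker lists in the limma fit with TMM. The 95% bootstrap interval of 2.39 to 2.76 resamples these RNAs, not libraries, and takes the RNAs as independent. A pull-down for tagged ribosomes would remove such RNA in full only if nothing else were carried along. A difference between the cell types, which the design names, stays open as untested.

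Other splits of the libraries, 40 with the real one, asked whether random groupings reach the real count. They did not keep libraries of the same title number together, and can show no smaller share than 1 in 40. At that level, only the real split reached the count of rhythmic genes in PV-titled (404, highest other 1) and C-titled libraries (3518, highest other 119) and in both (280, highest other 0). The same held for sex in PV-titled (4, highest other 1) and C-titled libraries (24, highest other 0). For the prefix contrast (11419 genes, highest other 0) and at least 2-fold differences (2936, highest other 0) the other splits say little about chance. Their fits held no term for the real prefix, so its difference stayed in the spread and worked against calls. For rhythm differences between the sexes the real count was 0, which all 40 splits reach by definition, so chance could not be excluded. The highest other was 1 in PV-titled and 783 in C-titled libraries, and 783 points to some structure of the samples, whose source was not tested. For the list tests 2 splits, the real one among them, gave at least the real 41. Their prefix tests also held no term for the real prefix, so its difference stayed in the data. The summed count therefore cannot decide on chance. The other splits gave 6 to 48 calls with the preset correlation, with a median of 26, so a pass with the preset value alone says little. With an estimated correlation the real count was 9 and the highest other 1.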
